A study of Rattus norvegicus with 6 samples.

How the data were processed

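The data are 6 arrays of primary rat cardiac fibroblast cultures, 3 treated with water and 3 with pertussis toxin (PTX) for 24 h. Groups and replicate numbers come from the sample titles. Per the labels' protocols, total RNA was isolated on a silica membrane and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays. Per the submitters' processing notes, the authors analysed the arrays with GCOS, the Affymetrix software; its version, scaling target and detection calls are not given in the sources used here. The deposited values are linear probe set intensities, 1 column per array and 8740 probe sets, with no control probe sets and 0 further columns of per-sample values. The 2% trimmed means of the 6 arrays lay between 493 and 495, as after scaling to a common target, so the deposited intensities were used without further scaling. No pair of arrays held identical values. GCOS signals near the background are noisy and carry no lower bound here, since detection calls were not used.

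Probe sets were named through the platform annotation. Of the 8740 probe sets, 7006 have 1 gene symbol, 308 have several and 1426 have none, and genes were named only from those with 1. The symbols of 6985 of the 7006 were updated through the Entrez identifier with a RefSeq gene table of the rat assembly GRCr8. That table was used for names only, and no coordinates are given, because the arrays have no genome build.

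Signals were analysed as log2(signal + 16), so fold changes are on that scale and understate the change of low signals. Probe sets whose mean log2 value over the 6 arrays lay under the 40th percentile were left out, which left 5244 probe sets of 3150 genes. Each was tested between PTX and control with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Means and SDs are of the signals, and the SE of a log2 change is limma's moderated one.

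Gene lists for inflammation, matrix, G protein signalling, metabolism, stress and cell types were fixed before the data were examined, as were the test, the filter, the rule for named genes and most alternatives. Each gene was represented by its probe set with the highest mean. The 21 lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 21 lists; 1 of these lists and its genes are not reported here. Camera with an estimated correlation and fry were run beside it. None of the 8 lists that passed with the preset correlation passed with the estimated one. The estimated correlation was negative for complement (-0.052), chemokines (-0.067) and cholesterol (-0.0069), so their loss does not come from correlation between members. The test with an estimated correlation therefore differs from the preset one in more than the correlation. For the other lists of the 8 the estimated correlation was 0.032 to 0.21, and how much of their loss comes from it was not separated. Fry, which asks only whether the genes of a list move one way on balance, passed for 6 of these 8, with adjusted p of 0.0123 for complement to 0.0320 for NF-kB; the exceptions were oxidative phosphorylation (0.246) and cardiomyocyte markers (0.267). It also passed for macrophage and leukocyte markers (0.0156).

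The named genes are the 12 largest changes per direction among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap of the groups, or the 6 with the smallest p where fewer than 6 pass. To these were added up to 4 members per gene list with the smallest p, 14 genes tied to the treatment, and from the cell type markers the member with the smallest p and the one with the highest mean. Other list members given are examples chosen after their values were seen, as are the genes named only in the closing section.

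The procedure was tested on simulated data with variances drawn from the fit to these arrays. Over 20 simulations of 5244 probe sets, 200 of them changed, limma recovered 8.21% of the changes of 1.5-fold, 47.6% of those of 2-fold and 90.5% of those of 4-fold, and 4.75% of its calls were false. Camera found 100% of lists of 20 genes shifted by 0.5 and 5% of unshifted ones. The simulated values were independent between probe sets, with no array that stood apart and no shift of a probe set class. These rates therefore need not hold for the real arrays, which have both.

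The alternatives tried were pseudocounts of 1 and 64, no filter and a 60th percentile filter, scaling to a common median, quantile and cyclic loess normalization, the replicate number as a block, eBayes without a trend and with robust variances, a fold of at least 1.5, and each array left out in turn. For lists, an estimated correlation and the mean of all probe sets of a gene were tried as well. Array quality weights, tests without the probe sets named rc_AA799 or rc_AA800, and tests without these and those named rc_AA892, rc_AA893 or rc_AA894 were added after seeing the data.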

Results

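Transcript levels were measured in primary cultures of cardiac fibroblasts from the ventricles of newborn Sprague-Dawley rats. Of the 6 samples, 3 received water as control and 3 received pertussis toxin (PTX) for 24 h. PTX is a bacterial toxin that ADP-ribosylates G proteins of the Gi and Go families and uncouples them from their receptors; its dose is not given in the sources used here. Each sample was hybridised to its own 1-colour Affymetrix array, and the comparison asks which transcripts differ between PTX and water. The median signal per array lay between 63.1 and 68.85 over 8740 probe sets, and the number of arrays limits the precision. The labels do not say whether the 3 samples of a group came from separate isolations of cells, so the p-values measure only the spread between these samples, which may be technical.

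Pla2g2a, Lcn2, C3 and Ccl2 rose with PTX. Pla2g2a, which encodes a secreted phospholipase A2 of the acute phase response, went from a signal of 301 ± 217 in the controls to 4787 ± 246 with PTX (SD, n = 3 each). This was 17.5-fold, a log2 change of 4.13 ± 0.40 (SE), with a limma adjusted p of 0.0217. Lcn2, encoding a lipocalin that withholds iron from bacteria, rose 3.14-fold, from 655 ± 99.9 to 2087 ± 242 (adjusted p = 0.0217). C3, the central complement component, rose 2.53-fold, from 954 ± 146 to 2425 ± 232 (adjusted p = 0.0429), and Ccl2, a chemokine that attracts monocytes, rose 3.66-fold, from 821 ± 259 to 2947 ± 37.3 (adjusted p = 0.0429). For each of these 4 genes all 3 PTX arrays lay above all 3 control arrays. A second probe set of C3 had a log2 change of 1.59 (adjusted p = 0.0579) and a second one of Ccl2 a log2 change of 1.52 (adjusted p = 0.0635), both just above the threshold.

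These 4 were the only probe sets past an adjusted p of 0.05 among the 5244 tested with limma, and 0 probe sets were lower. At an unadjusted p under 0.05 there were 418 higher and 242 lower probe sets, 660 in all, where chance alone gives 262.2. Without the probe sets whose names begin with rc_AA799 or rc_AA800 there were 304 higher and 253 lower among 4972 tested. Without these and those beginning with rc_AA892, rc_AA893 or rc_AA894 there were 207 higher and 261 lower among 4619 tested. The filter on low signals was applied anew after each removal, so the chance count above is not theirs. The values of the 2 groups did not overlap for 22.6% of the tested probe sets, against 10% by chance. The calls depend on the model and on single arrays. No probe set passed with eBayes without a trend (smallest adjusted p = 0.0720) or with the replicate number as a block (smallest adjusted p = 0.0567). Without control replicate 1, 98 probe sets were higher and 18 lower, and without control replicate 3, 29 were higher. Without PTX replicate 1, 2 or 3 no probe set passed (360, 375 and 376 at an unadjusted p under 0.05), and without control replicate 2 Lcn2 (adjusted p = 0.0762) and C3 (adjusted p = 0.118) were lost.

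**Figure D1:**
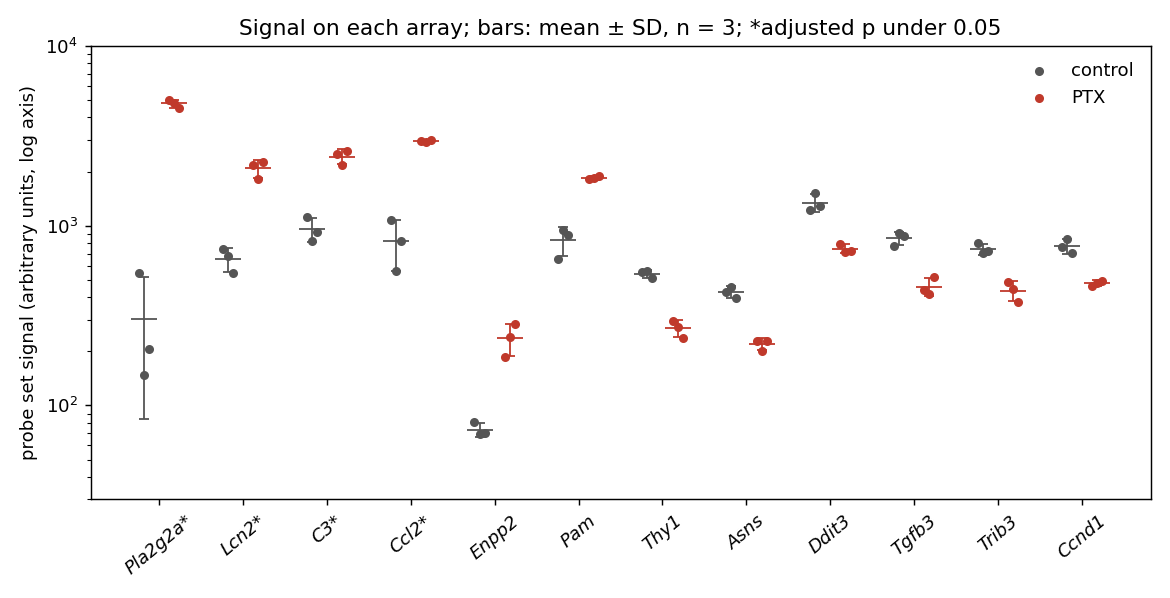
Probe set signal (arbitrary units, log axis) on each of the 3 control and 3 PTX arrays for the 6 higher and 6 lower genes with the smallest p whose groups do not overlap; points are arrays, and bars are the mean ± SD (n = 3). The genes with a star passed an adjusted p of 0.05, and Pla2g2a had the largest change among them, from 301 to 4787.

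Control replicate 1 stood apart from the other arrays. Its Pearson correlation with the other 5, across all probe sets on the log2 scale, was 0.952 to 0.960, against 0.978 to 0.985 among those 5. Probe sets whose names begin with rc_AA799 or rc_AA800 had low signals on it, and those beginning with rc_AA892, rc_AA893 or rc_AA894 did so to a lesser degree. The 375 tested members of the rc_AA799 and rc_AA800 class had a median log2 change of 0.56 with PTX, and 88.8% were positive. Without control replicate 1 their median was 0.27, and 50 of the 98 higher calls made without that array came from this class. The 420 probe sets of the other 3 prefixes had a median of 0.29, with 79.0% positive, and 0.16 without control replicate 1, where they held 16 of the 98 higher calls. The 174 probe sets beginning with rc_AA891 had a median of 0.17, with 68.4% positive. The 2960 probe sets not named rc_ went the other way, with a median of -0.10 and 34.8% positive, or -0.05 without control replicate 1. Counts of negative members in lists read mainly by such probe sets are to be set against that share. Pam, C1r, Serping1, Stat2, Irf7, Cd40, Gng10, Pde4b, Sdha, Atp5pb, Actn2, Nppb and Ccn1 are measured by rc_AA799 or rc_AA800 probe sets here, and Plod2, Postn and Pdia6 by probe sets of the other 3 prefixes.

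**Figure D2:**
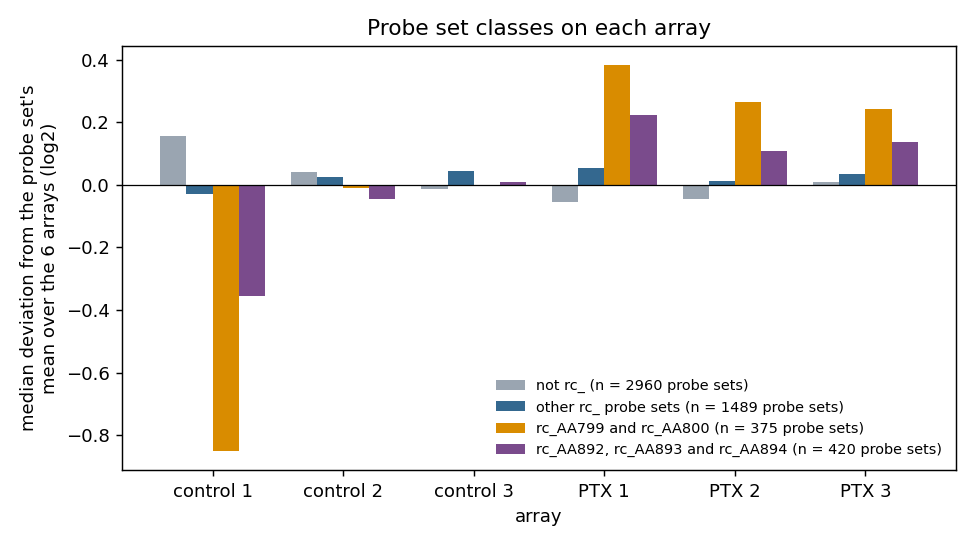
Median deviation (log2) of each class of probe sets from the probe set's own mean over the 6 arrays, by array. Bars show 4 classes by the start of the probe set name; the rc_AA799 and rc_AA800 class lay at -0.85 on control replicate 1 and at 0.24 to 0.38 on the PTX arrays, and the rc_AA892, rc_AA893 and rc_AA894 class at -0.35 and at 0.11 to 0.22.

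Beyond these 4 genes, among higher probe sets with 1 gene symbol those with the smallest p were of Enpp2 and Pam, which did not pass. Enpp2 encodes autotaxin, the enzyme that makes lysophosphatidic acid, and had signals of 73.2 ± 6.34 and 237 ± 48.6 (log2 change 1.49, adjusted p = 0.0530). Pam, a peptide-amidating enzyme, had a log2 change of 1.15 (adjusted p = 0.0635) on a probe set of the class described above, and its other probe sets averaged 0.07. No lower probe set passed, the smallest adjusted p being 0.0743 for Thy1, a surface glycoprotein of fibroblasts, with 541 ± 27.3 in the controls and 269 ± 28.9 with PTX (log2 change -0.97). Next came Asns, which makes asparagine, with 427 ± 31.7 and 219.5 ± 16.8 (-0.91, adjusted p = 0.0876), and Ddit3, a transcription factor of the integrated stress response, with 1341 ± 157 and 745 ± 42.3 (-0.83, adjusted p = 0.114). Tgfb3 (-0.88), Trib3 (-0.75) and Ccnd1 (-0.66) followed, with adjusted p of 0.114, 0.184 and 0.184. Other probe sets had -0.59 for Thy1, -0.77 for Tgfb3 and -0.89 for Trib3, with overlapping groups for Thy1 and Trib3. Ccnd1 had -0.48 on its brightest probe set (adjusted p = 0.351), and -0.26 and -0.24 on others with overlapping groups. Without control replicate 1, Enpp2, Pam and all 6 of these lower genes passed on the probe set first given, with adjusted p between 0.00106 for Pam and 0.0275 for Trib3. The brightest probe set of Ccnd1 did not (adjusted p = 0.157).

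Genes of complement and the acute phase rose as a group. All 9 measured members of the list had positive log2 changes, with a median of 0.78 (camera adjusted p = 1.01e-05; adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, 6 rose: C3, C1r, C1s, Hp, Cp and Serping1. C1s, a protease of the first complement component, had 3233 ± 606 in the controls and 5485 ± 111 with PTX (log2 change 0.78), and Hp, encoding haptoglobin, had 73.5 ± 11.1 and 149 ± 25.9 (0.88). C1r went from 4864 ± 994 to 9342 ± 967 (0.95), on a probe set of the class that was low on control replicate 1, as was that of Serping1 (1.30, or 0.65 without that array). Over all probe sets tested, the list's probe sets gave 0 calls, since the C3 probe set that passed is not its brightest.

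Interferon response genes were shifted upwards too. All 11 measured members were positive, with a median log2 change of 0.37 (camera adjusted p = 0.000389; adjusted p = 0.240 with an estimated correlation). Adjusted over the list alone 3 rose, Stat2 (1.03), Irf7 (1.07) and Eif2ak2 (0.65), and over all probe sets 0. Stat2 and Irf7, transcription factors of the interferon response, are both read by probe sets of the class that was low on control replicate 1. Eif2ak2, the kinase activated by double-stranded RNA, is not, and had 171 ± 39.5 and 274 ± 14.3. Without control replicate 1 Stat2 had 0.74, Irf7 0.72 and Eif2ak2 0.53. Another Irf7 probe set of the class had 0.13 with overlapping groups (limma adjusted p = 0.832). B2m, the light chain of class I histocompatibility antigens, had a log2 change of 0.33 (0.20 without control replicate 1) and Tap1, which loads them with peptides, 0.37, and neither passed.

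Chemokines and the NF-kB and TLR4 response genes also shifted upwards. Of 5 measured chemokines, 2 rose when adjusted over the list alone, Ccl2 (1.52) and Cxcl6, which went from 47.7 ± 22.8 to 106 ± 10.1 (log2 change 1.01), and 0 over all probe sets on each gene's brightest probe set. The chemokine list had a median of 0.75 and a camera adjusted p = 0.0253 (adjusted p = 0.240 with an estimated correlation). That median is the log2 change of Ccl3, with mean signals of 42.3 and 70.9 and overlapping groups (limma adjusted p = 0.507). Over the settings tried, Ccl3 ranged from 0.17 to 1.21. The control signals of Ccl3 and Cxcl6 lay near the low end of the tested signals. Cx3cl1 (0.25) and Ccl20 (-0.10) did not pass, so Ccl2 was the only brighter chemokine that rose. Among 17 measured NF-kB and TLR4 response genes, 5 rose and 2 fell adjusted over the list alone, and 1, Lcn2, rose over all probe sets (median 0.20, camera adjusted p = 0.0415; adjusted p = 0.437 with an estimated correlation). The 5 were Lcn2, Nfkbia, Icam1, Vcam1 and Il1b. Nfkbia, the inhibitor that NF-kB itself induces, had 253 ± 13.4 and 446 ± 40.7 (0.78), and the adhesion molecules Icam1 and Vcam1 had log2 changes of 0.57 and 0.82. The 2 that fell were Nos2, the inducible nitric oxide synthase, with 66.6 ± 15.1 and 20.3 ± 9.52 (-1.20), and Il15 (-0.49). Another probe set of Nos2 had -0.42 with overlapping groups (adjusted p = 0.640), and both lie near the low end of the tested signals. The chemokine call was lost with no filter on low signals (adjusted p = 0.160), without control replicate 2 (adjusted p = 0.0514) and without control replicate 3 (adjusted p = 0.0747). The NF-kB call was lost without control replicate 2 (0.0658), control replicate 3 (0.299), PTX replicate 2 (0.0588) or PTX replicate 3 (0.0539), as adjusted p, under 3 scalings between arrays (0.0527 to 0.0707), with the replicate block (0.0748) and with eBayes without a trend (0.0544).

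**Figure D3:**
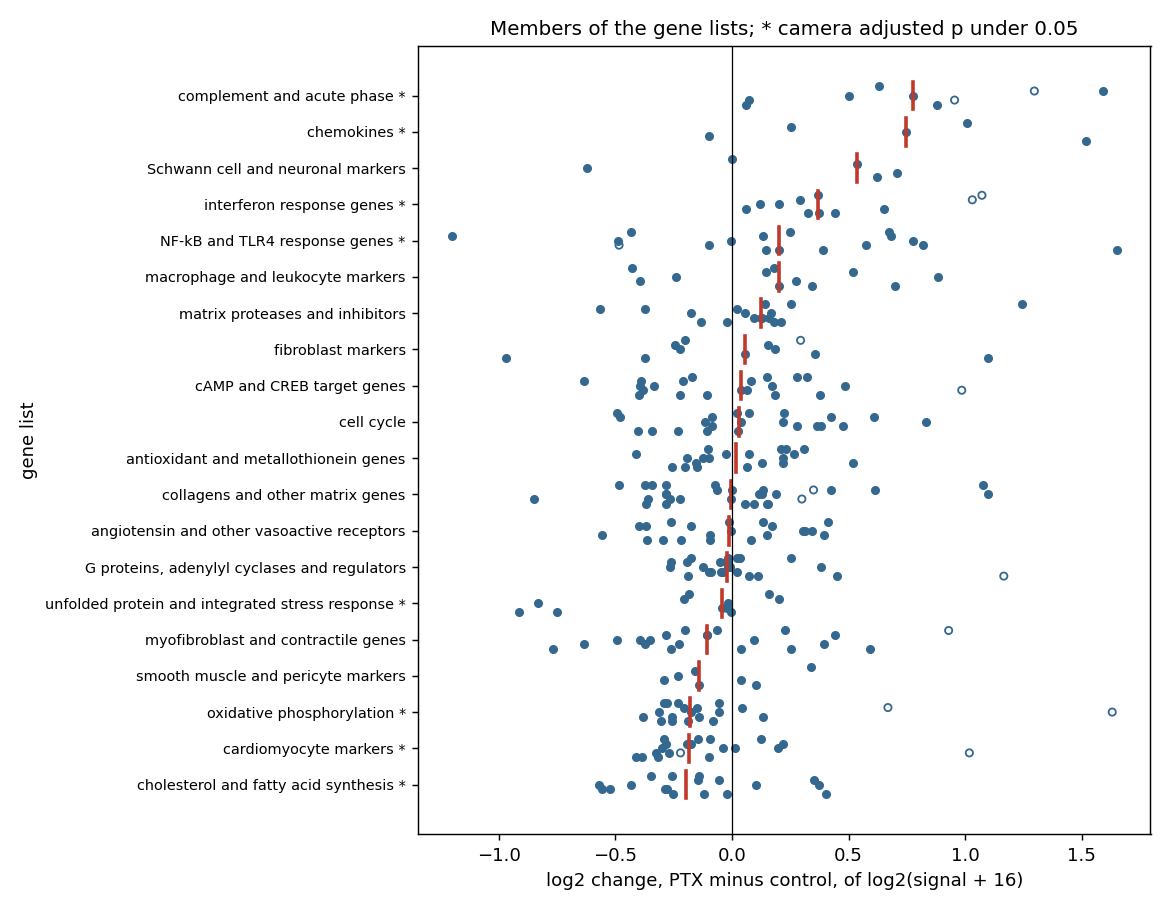
Log2 change (PTX minus control) of each measured member of 20 of the 21 tested gene lists, on the scale of log2(signal + 16). Points are genes, open points are probe sets of the rc_AA799 and rc_AA800 class, vertical lines are list medians, and stars mark lists with a camera adjusted p under 0.05; all points of the complement and interferon lists lie above 0.

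The list of unfolded protein and integrated stress response genes was shifted downwards (camera adjusted p = 0.0253; adjusted p = 0.276 with an estimated correlation). Of its 11 measured members 3 fell adjusted over the list alone, and 0 over all probe sets: Asns, Ddit3 and Trib3, which are targets of the transcription factor ATF4. Among chaperones of the endoplasmic reticulum, the log2 change was -0.01 for Hspa5, -0.04 for Calr and 0.16 for Hsp90b1, and the list's median was -0.04. Pdia6, a folding enzyme gene of the list, had -0.21 with groups that did not overlap (limma adjusted p = 0.467). Without control replicate 1 the median, Hspa5 and Pdia6 were all at -0.25. The call was lost without control replicate 2 (adjusted p = 0.0658), without control replicate 3 (adjusted p = 0.146) and without the probe sets of the 5 prefixes named above (adjusted p = 0.0753).

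Genes of cholesterol and fatty acid synthesis were shifted downwards as a list, with 14 of 18 measured members negative and a median of -0.20 (camera adjusted p = 0.0253; adjusted p = 0.240 with an estimated correlation). Of all tested probe sets not named rc_, such as those of Mvk, Mvd, Fdps and Cyp51 given first below, 34.8% were positive, with a median of -0.10. Without control replicate 1 the list's median was -0.22 and that of those probe sets -0.05. No member passed adjusted over the list alone or over all probe sets, and 5 had an unadjusted p under 0.05. Among these were enzymes of the mevalonate pathway, Mvk, with 227 ± 15.1 and 147.5 ± 7.81 (log2 change -0.57), Mvd (-0.56) and Fdps (-0.52), and the sterol demethylase Cyp51 (-0.43). Without control replicate 1 Mvd had -0.36 and Fdps -0.34. Another probe set of Fdps had 0.24, or -0.13 without that array. A second probe set of Mvk had -0.07 with overlapping groups (limma adjusted p = 0.909), or -0.32 without that array. The call was lost without control replicate 3 (adjusted p = 0.146) and without PTX replicate 2 (adjusted p = 0.0518).

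Oxidative phosphorylation genes and cardiomyocyte markers were shifted downwards by small amounts. Of 20 measured oxidative phosphorylation genes 16 were negative (median -0.18, camera adjusted p = 0.0303; adjusted p = 0.437 with an estimated correlation), and 0 passed adjusted over the list alone or over all probe sets (1 higher and 1 lower at an unadjusted p under 0.05). The mean was -0.04, since Sdha (1.63) and Atp5pb (0.67), from the probe set class that was low on control replicate 1, were positive (0.69 and 0.29 without that array), whereas Ndufa4 had -0.26 and Ndufv2 -0.38. The oxidative phosphorylation call was lost without control replicate 1 (0.136, with a median of -0.10), 2 (0.0658) or 3 (0.0733) and without PTX replicate 1 (0.173), as adjusted p. It was also lost with no filter (0.0661), with the mean of a gene's probe sets (0.138), without a trend (0.0560), with array quality weights (0.0943) and with quantile (0.334) or cyclic loess (0.437) normalization, where the median was -0.11 and -0.08.

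Transcripts of cardiomyocytes were among the brightest on all 6 arrays. Of the 20 measured cardiomyocyte markers, 8 lay in the top 1% of probe sets on every array and 14 in the top 5%, which gives no share of cells, since signals of different probe sets are not comparable as transcript levels. Myl2, a ventricular myosin light chain, had 52335 ± 15205 in the controls and 42453 ± 4037 with PTX (log2 change -0.27, or -0.04 without control replicate 1), and Nppa, which encodes atrial natriuretic peptide, 36923 ± 8572 and 29147 ± 2148 (-0.32, or -0.14 without that array). Col3a1, a fibrillar collagen of fibroblasts, had 20222 ± 1932 and 17300.5 ± 1486. The cardiomyocyte markers had a median log2 change of -0.18, or -0.09 without control replicate 1, with 15 of 20 negative (camera adjusted p = 0.0303; adjusted p = 0.524 with an estimated correlation) and 0 calls adjusted over the list alone or over all probe sets, with 1 lower at an unadjusted p under 0.05. This call was lost without control replicate 1 (0.154), 2 (0.0514) or 3 (0.0507), without PTX replicate 3 (0.193) and without those 5 prefixes (0.0753), as adjusted p. It was also lost with no filter (0.0982), a 60th percentile filter (0.0607), common median scaling (0.0527), no trend (0.0560) and array quality weights (0.0676), and the median was -0.01 with quantile and -0.06 with cyclic loess normalization (adjusted p = 0.964 and 0.808).

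Among markers of other cell types, the 11 macrophage and leukocyte markers had a median of 0.20, with 8 of 11 positive (camera adjusted p = 0.122; fry adjusted p = 0.0156). With camera they passed without the rc_AA799 and rc_AA800 probe sets (adjusted p = 0.0477), also with control replicate 1 left out (adjusted p = 0.0300), as Schwann cell and neuronal markers did with both left out (adjusted p = 0.0478). That class read 0 members of either list, and its removal takes mostly rising probe sets out of the genes that camera compares a list with. These passes therefore need not reflect the markers themselves. The Schwann cell and neuronal markers had a median signal of 87.3. Of the macrophage markers, adjusted over the list alone, 1 rose, the Fc receptor gene Fcgr2b, from 325 ± 28.2 to 612 ± 31.1 (log2 change 0.88). C1qb and C1qc, complement genes of macrophages, had log2 changes of -0.39 and -0.24. The 11 fibroblast markers had a median of 0.06 (camera adjusted p = 0.844), with 1 higher and 1 lower adjusted over the list alone, the proteoglycan gene Lum, from 1325 ± 500 to 2697 ± 76.7, and Thy1 (-0.97). Smooth muscle and pericyte markers (median -0.14, or -0.04 without control replicate 1, camera adjusted p = 0.844) and Schwann cell and neuronal markers (0.54, 0.271) gave 0 calls, with 0 and 1 at an unadjusted p under 0.05. The 4 measured endothelial, 2 erythroid and 1 mast cell markers were too few to test as lists, with medians of -0.11, 0.04 and -0.08 (0.21, 0.09 and -0.18 without control replicate 1).

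The matrix genes did not move as a list. The 30 measured collagens and other matrix genes had a median of -0.00 (camera adjusted p = 0.844), and adjusted over the list alone 2 rose and 1 fell, with 0 over all probe sets. Plod2, which hydroxylates collagen lysines, on an rc_AA892 probe set, had 1522 ± 217 and 2322 ± 112 (log2 change 0.61), and the other was Lum. Eln, which encodes elastin, fell, from 4847 ± 415 to 2724 ± 576 (-0.85). Postn, on an rc_AA894 probe set, had a log2 change of 1.07 and did not pass. Among the 21 myofibroblast and contractile genes (median -0.11, camera adjusted p = 0.226) only Tgfb3 fell adjusted over the list alone (-0.77 on its brightest probe set), and Tagln, a smooth muscle actin-binding protein, had -0.35 (-0.19 without control replicate 1). The 17 matrix proteases and inhibitors (0.13, 0.70) gave 0 calls, with 1 higher and 1 lower at an unadjusted p under 0.05; Mmp9 had 24.9 ± 15.0 and 77.8 ± 21.7, close to the low end of the tested signals.

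Genes tied to the toxin's targets and to angiotensin signalling gave few calls. The 21 measured angiotensin and other vasoactive receptors had a median of -0.01 (camera adjusted p = 0.884), with 0 calls and 0 at an unadjusted p under 0.05 on each gene's brightest probe set. Other probe sets of Agtr1a (log2 change 0.52, limma unadjusted p = 0.00491) and Agtr1b (-0.81, unadjusted p = 0.0263) were under 0.05, with groups that did not overlap. Agtr1a, the type 1 angiotensin II receptor, had 1139 ± 166 and 1410 ± 44.0 on its brightest probe set (log2 change 0.31, adjusted p = 0.417), and its other 3 tested probe sets had 0.52, 1.14 and 0.23 without passing, the 1.14 being 0.35 without control replicate 1. Agtr1b had a log2 change of -0.17 and changed sign to 0.04 without control replicate 3, its other 2 tested probe sets had -0.81 (adjusted p = 0.360) and -0.09, and Agtr2 was below the filter on low signals. Of the 25 G proteins, adenylyl cyclases and regulators (median -0.02, camera adjusted p = 0.978) 1 rose adjusted over the list alone, the G protein gamma subunit gene Gng10 (1.17), on a probe set of the class that was low on control replicate 1. On each gene's brightest probe set, the substrates of the toxin had log2 changes of -0.26 (Gnai1), 0.02 (Gnai2) and 0.07 (Gnao1, or -0.12 without control replicate 1). On other probe sets Gnai2 had 0.39 with groups that did not overlap (limma adjusted p = 0.454) and -0.16, and Gnao1 had 0.04. None of these passed the threshold, and no probe set is named for Gnai3. Tlr4 had 31.9 ± 17.8 and 44.2 ± 2.10 (0.39, adjusted p = 0.578), and Nfkb1 (-0.10) and Il1rl1 (-0.04) did not pass either. Il1b had 49.9 ± 11.8 and 88.7 ± 13.2 on its brighter probe set (0.67, adjusted p = 0.324) and 1.55 on the other (adjusted p = 0.204).

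A further 3 lists had medians near 0 and gave 0 calls adjusted over the list alone and over all probe sets. They were cAMP and CREB target genes (21 measured, median 0.04, camera adjusted p = 0.844), cell cycle genes (22, 0.03, 0.830) and antioxidant and metallothionein genes (20, 0.02, 0.978). At an unadjusted p under 0.05, 1 cAMP target and 4 cell cycle genes were higher, and 2 cell cycle genes and 1 antioxidant gene lower. Among cAMP targets Fos had -0.39 and Nr4a2 -0.64 (-0.26 and -0.42 without control replicate 1), and Pde4b had 0.99 on a probe set of the class that was low on control replicate 1 (0.52 without that array), against -0.13 on its others. Among cell cycle genes Stmn1 had 0.61 and Pcna -0.35, and among antioxidant genes Gstp1 had -0.41. The sign of the median, the mean and the camera test differed for the cAMP, antioxidant, fibroblast marker, G protein and matrix lists, none of which passed, and no direction is given for them.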

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

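Array quality weights and the tests without the rc_AA799 and rc_AA800 class, or without it and the rc_AA892, rc_AA893 and rc_AA894 probe sets (5 prefixes), were chosen after seeing the data. Complement (adjusted p 2.66e-10 to 0.00149) and interferon genes (4.1e-05 to 0.0133) passed in all 21 alternatives other than an estimated correlation. Of all list results under alternatives, 409 kept their side of the threshold, 48 lost it, 3 gained it and 0 changed direction with a call. Of those for named genes, 1478 kept their direction and side, 73 gained a call, 27 lost one and 9 changed sign, none of these called. Most results that kept their side were of lists and genes that were never called. All 48 list losses fell on the 8 called lists, and all 27 gene losses on the 4 called probe sets. Over 21 settings, the reported one included, Pla2g2a passed in 16, Lcn2 in 15, and the called probe sets of C3 and Ccl2 in 13 each. Where a call or count changed, the cause was not tested. Signals near the low end, such as those of Tlr4, Mmp9 and Il1b, limit what these arrays can show.

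The 4 higher and 0 lower probe sets became 2 higher with a pseudocount of 1, 7 with 64, 2 with quantile normalization, 9 with robust eBayes, 0 with eBayes without a trend (615 at an unadjusted p under 0.05) and 8 without the class, and 9 higher and 2 lower without the 5 prefixes. Array quality weights, at 0.186 for control replicate 1, gave 66 higher and 15 lower. Of these 81, 77 were also called without that array. Leaving out both that array and the class gave 34 higher and 10 lower. With 1 array left out the counts ranged from 0 to 98 higher and from 0 to 18 lower.

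With the replicate number as a block, 0 probe sets passed (552 at an unadjusted p under 0.05), and of the 8 list calls that of NF-kB was lost (adjusted p = 0.0748). The labels do not say whether the numbers pair the samples. Deviations from the group means correlated across probe sets at -0.09, -0.11 and -0.01 within a number, and at -0.05 to 0.10 between numbers. This cannot decide it, since the deviations of a group sum to 0 and those of the controls are weighted by control replicate 1.

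With an estimated correlation the camera adjusted p were 0.133 for complement, 0.240 for interferon, chemokines and cholesterol, 0.276 for the stress response, 0.437 for NF-kB and oxidative phosphorylation and 0.524 for cardiomyocyte markers. NF-kB had 0.0527 with common median scaling, 0.0707 with quantile, 0.0596 with cyclic loess and 0.0544 without a trend. Chemokines had 0.160 with no filter; with the 60th percentile filter too few of them, and of the Schwann cell and neuronal markers, were left to test. Oxidative phosphorylation had 0.0661 with no filter, 0.334 with quantile, 0.437 with cyclic loess, 0.0560 without a trend, 0.138 with the mean of probe sets and 0.0943 with weights. Cardiomyocyte markers had 0.0982 with no filter, 0.0607 with the 60th percentile filter, 0.0527 with common median scaling, 0.964 with quantile, 0.808 with cyclic loess, 0.0560 without a trend, 0.0676 with weights and 0.241 without both control replicate 1 and the class. Without the 5 prefixes the stress response and cardiomyocyte markers had 0.0753. Macrophage markers passed without the class (0.0477) and without both (0.0300), and Schwann cell and neuronal markers without both (0.0478). The class read 0 members of either list.

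With 1 array left out, the adjusted p ranged from 0.00306 to 0.299 for NF-kB, 0.00306 to 0.0747 for chemokines, 0.00306 to 0.146 for cholesterol, 0.00126 to 0.146 for the stress response, 0.0109 to 0.173 for oxidative phosphorylation and 0.0229 to 0.193 for cardiomyocyte markers. Among uncalled genes, Myl2 was at 0.041 with quantile normalization, and Gnao1 at -0.060 with weights and -0.12 without both control replicate 1 and the class. With 1 array left out Gnao1 ranged from -0.12 to 0.18, Gnai2 from -0.045 to 0.14, Agtr1b from -0.32 to 0.040 and Il1rl1 from -0.16 to 0.080.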

Other observations

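The tests of control replicate 1 alone, of the cardiomyocyte transcripts and of macrophages were chosen after their results were seen.

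Without control replicate 1 the 116 probe sets called also held genes outside the lists, and the ones named here were chosen after their values were seen. Reg3b, a secreted lectin, rose by a log2 change of 1.15, and Igfbp3, which binds insulin-like growth factors, by 0.75 and 0.49 on its 2 probe sets. Plpp1, a phosphatase of lipid phosphates such as lysophosphatidic acid, rose by 0.69 and 0.61, and the P450 gene Cyp1b1 and the guanine deaminase gene Gda by 0.61 and 0.74. Among the lower ones were the hexokinase gene Hk2 (-0.61), the netrin receptor gene Unc5b (-0.53), the embryonic myosin gene Myh3 (-0.57) and Capn6 (-0.85). Phgdh (-0.60) and Psat1 (-1.15), which encode enzymes of serine synthesis, were lower too. With all 6 arrays none of these passed, with log2 changes of 0.98 for Reg3b, 0.36 and 0.48 for Igfbp3, 0.60 and 0.52 for Plpp1, -0.61 for Hk2 and -0.70 for that probe set of Psat1.

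The probe sets named rc_AA799 or rc_AA800 had higher values with PTX, with a median log2 change of 0.56. In 42 genes that have such a probe set and another one, the class probe set was higher in 40 (exact sign test, two-sided p = 4.11e-10), by a median of 0.57 (95% bootstrap interval 0.44 to 0.87). Without control replicate 1 the class probe set was higher in 34 of the 42, by a median of 0.36. The other probe sets of these genes had a median of -0.075 (-0.14 to 0.04), which argues against a rise of the transcripts themselves. Control replicate 1 alone does not account for all of it, since without that array the class still exceeded all other probe sets by 0.30 (0.27 to 0.35), against 0.60 with it. A shift of the probe set class rather than of its genes may therefore underlie the pattern, and the rc_AA892, rc_AA893 and rc_AA894 probe sets had a smaller shift of the same kind, with a median of 0.29. The sign test and the intervals take genes or probe sets of the same arrays as units and do not measure the spread between arrays. They cannot tell whether the shift left without control replicate 1 goes with PTX or varies between arrays.

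Cardiomyocyte transcripts were among the brightest in samples labelled as fibroblasts. At least 8 of 20 cardiomyocyte markers were in the top 1% on each array, as cardiomyocyte RNA in the cultures would give, though no share of cells follows from signals of different probe sets. Of 6 markers taken to have no close paralog expressed in fibroblasts, 4 were in the top 5% on every array: Nppa, Nppb, Tnni3 and Csrp3. Csrp3 has the family members Csrp1 and Csrp2, both in the list of myofibroblast genes, and Nppb is read by an rc_AA799 probe set. The ranks argue against cross-hybridisation between paralogs for Nppa, Nppb and Tnni3 and leave it open for Csrp3 and the other markers. Arrays of cardiomyocyte cultures under a fibroblast label cannot be told apart from a mixed culture, since ranks of different probe sets do not measure composition; 1 fibroblast marker, Col3a1 or Dcn, was in the top 1% on each array. No sample of either pure cell type is at hand to decide this.

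The complement, interferon, chemokine and NF-kB lists shifted upwards. All 4 passed camera at the preset correlation without the rc_AA799 and rc_AA800 probe sets, and none at an estimated correlation with all probe sets. The removal tests little for chemokines and NF-kB genes, of which the class read 0 and 1 (Cd40, -0.48). It read 2 complement and 2 interferon genes. The removal also takes mostly rising probe sets out of the genes that camera compares a list with. Without control replicate 1 the median of the 42 members was 0.34, against 0.38 with it. This argues against that array as the whole source, and the passes against the class as the whole source for complement and interferon genes. More macrophages in the PTX cultures stay open: 8 of 11 macrophage markers were positive, with a median of 0.20, while C1qb and C1qc had a mean log2 change of -0.32, whose 95% interval (-0.91 to 0.28) holds that median. A response of the cultured cells to PTX remains a hypothesis. Endotoxin in the toxin preparation stays open as well, since no sample received heat-inactivated toxin.

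Asns, Ddit3, Trib3, Phgdh, Psat1, Slc7a1 and Slc3a2, which are targets of the transcription factor ATF4, had log2 changes of -0.52 to -0.91. The hypothesis of lower ATF4 target genes was tested on the other targets in a list of 41 drawn up before their values were looked at, of which 16 were measured. The 9 not seen before had a median of -0.17, or -0.20 without control replicate 1, and 7 were lower (camera p = 0.00831; p = 0.0517 with an estimated correlation). At an unadjusted p under 0.05 there were 2, the amino acid transporter gene Slc7a5 (-0.49) and Eif4ebp1 (-0.53). Most of the 9 are read by probe sets not named rc_, which had a median of -0.10 with 34.8% positive, or -0.05 without control replicate 1. The shift of these 9 goes the way of the hypothesis, though it is small beside that of the 7 genes that prompted it. How far it exceeds that of probe sets of the same kind was not tested.

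The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4 probe sets and 8 lists, which 1 of the 10 splits reached in each case, and the highest of the others gave 0 probe sets and 1 list.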
